A study of Mus musculus with 12 samples.

How the data were processed

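Lungs of C57BL/6NCr mice, a C57BL/6 substrain, were profiled at 4 ages, written by months as 6M, 12M, 20M and 30M, with 3 libraries per age. Per the labels' protocols, total RNA was extracted with ISOGEN II, mRNA was taken by poly-A selection, and paired-end reads were made on an Illumina platform. The deposited table gives whole-number read counts per gene, without normalization. Per the submitters' processing notes, the tools were FastQC 0.11.7, Trimmomatic 0.38, HISAT2 2.1.0 and featureCounts, whose version is not given there, and the genome build was GRCm38 (mm10). The gene annotation release and whether counting used the strand are not given in the sources used here, so overlapping and antisense genes, and genes with near-identical copies, carry uncertain counts.

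The table lists 55487 genes with Ensembl identifiers, symbols and coordinates. Of these identifiers, 55227 are also in GENCODE M21 (GRCm38), and 99.4% of those have the same start and end there. That annotation and the GRCm38 sequence were used for gene GC content, which 18382 of the 18407 tested genes have. Coordinates are printed as the table gives them.

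Libraries are written as age and replicate number, both taken from their titles, and no replicate number occurs at more than 1 age. The labels do not say that each number is a separate animal, so p-values measure the spread between these libraries. Library totals ran from 12152066 to 15058628 counts. No pair of libraries of 1 age was a duplicate, as chi-square per gene between them was 6.66 to 49.9. At this depth 1 CPM is a few more than 10 counts per library, and intervals given for counts cover counting error only. Levels are CPM (counts scaled to a library of 1e+06) with TMM scaling, as mean ± SD over 3 libraries.

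Tests, gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. Genes were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 (robust fit, TMM, filterByExpr by age), with all 12 libraries in 1 fit. The comparisons were 12M, 20M and 30M against 6M, 20M against 12M, and 30M against 20M, with a joint test over all ages and a slope per month. A gene is called here when its Benjamini-Hochberg adjusted p is under 0.05. The common biological coefficient of variation was 0.236. Across all tested genes the median log2 change at 30M against 6M was 0.00284, and it lay between -0.0245 and 0.0207 under the alternatives.

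Lists of marker and pathway genes, 56 in all, were tested with camera of limma 3.58.1 (preset correlation 0.01) on log2 CPM with a prior count of 2, with adjustment over the lists within a comparison. Camera asks whether a list's genes move more than other genes. It was also run with the correlation estimated from the data, and fry, whose p asks whether a list's genes move on balance in 1 direction, was run beside it. Of 886 genes on any list, 32 are on more than 1. Gene Ontology terms given in the deposited table were tested for excess among higher genes with a one-sided exact hypergeometric test. The size limit was set at 10 to 500 genes among the 15094 tested genes with a term, though a term of 9 genes also entered. That test was added after the data were seen.

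Named genes are the 10 largest rises and falls at 30M against 6M among called genes with at least 1 CPM in the higher age and no overlap between the libraries. The same rule names 5 each way in other comparisons, 5 trend genes each way by adjusted p, and 2 segment genes of antigen receptors per direction. Up to 4 members of a list are named, those with the smallest p in that comparison, called or not. Predicted genes are counted but not named, except where a count of 5 or fewer holds them. Cdkn2a, Cdkn1a and the sex-linked genes Xist, Ddx3y, Uty, Kdm5d and Eif2s3y are always named.

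The gene test was tested on simulated counts for the 18407 genes with some genes changed in the 30M libraries. It recovered 4 of 67 genes changed 1.5-fold (5.97%), 32 of 67 changed 2-fold (47.8%) and 54 of 66 changed 4-fold (81.8%), and 9 of 99 calls were unchanged genes. Alternatives were DESeq2 1.42.0, limma voom with quality weights, DESeq2's size factors, other count filters, antigen receptor segments left out, only the 2 ages compared, 12M as reference, other age scales and each library left out in turn. Added after seeing the data were a removal of each library's GC trend, a term for the 3 libraries with a steep GC trend, and fits without those 3, without 12M_208 or without 20M_222.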

Results

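Gene expression in whole lung was measured by RNA sequencing in mice of 4 ages, to ask which transcripts differ with age. Each age had 3 libraries, named by age and replicate number, with 12152066 to 15058628 counts per library, and 18407 genes were tested. Libraries correlated with one another at r = 0.928 to 0.984 across genes. The first principal component of the 500 most variable genes held 31.6% of the variance (23.6% with 2000 genes). Its mean was -20.7 ± 4.31 at 6M and 10.3 ± 7.96 at 30M (SD, n = 3). Between these an exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 can give. At 12M and 20M the mean was -3.93 ± 12.5 and 14.3 ± 20, so that of 20M lay above that of 30M. The highest library was 20M_222 at 34.95.

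All libraries carried Y-linked transcripts, the sex of the mice not being in the labels. Ddx3y stood at 112 ± 6.48 CPM at 6M and 86.98 ± 6.75 at 30M, and Uty at 24.1 ± 2.78 and 19.6 ± 1.22. Kdm5d was at 30.1 ± 4.27 and 28.4 ± 4.99, and Eif2s3y at 66.99 ± 9.60 and 61.5 ± 9.56. Xist, the transcript of the inactive X chromosome, was at 1.94 ± 1.02 CPM at 6M and 1.52 ± 0.0599 at 30M, and none of the 5 was called (adjusted p = 0.512 to 0.955). Some libraries stood apart within their age. Relative to the 6M mean, expression followed gene GC content across genes with Spearman rho = 0.446 in 20M_221, 0.548 in 20M_222, 0.397 in 30M_220 and 0.265 in 12M_208, and -0.107 to 0.0902 in the other libraries. Genes are not independent replicates, so these rho describe the libraries. 20M_222 also held skeletal muscle transcripts, with the actin Acta1 at 1039 CPM against at most 2.13 CPM in any other library. Chi-square per gene was 36.9 and 31.9 between 12M_208 and 12M_206 and 12M_207, against 12.7 between those 2.

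**Figure D1:**
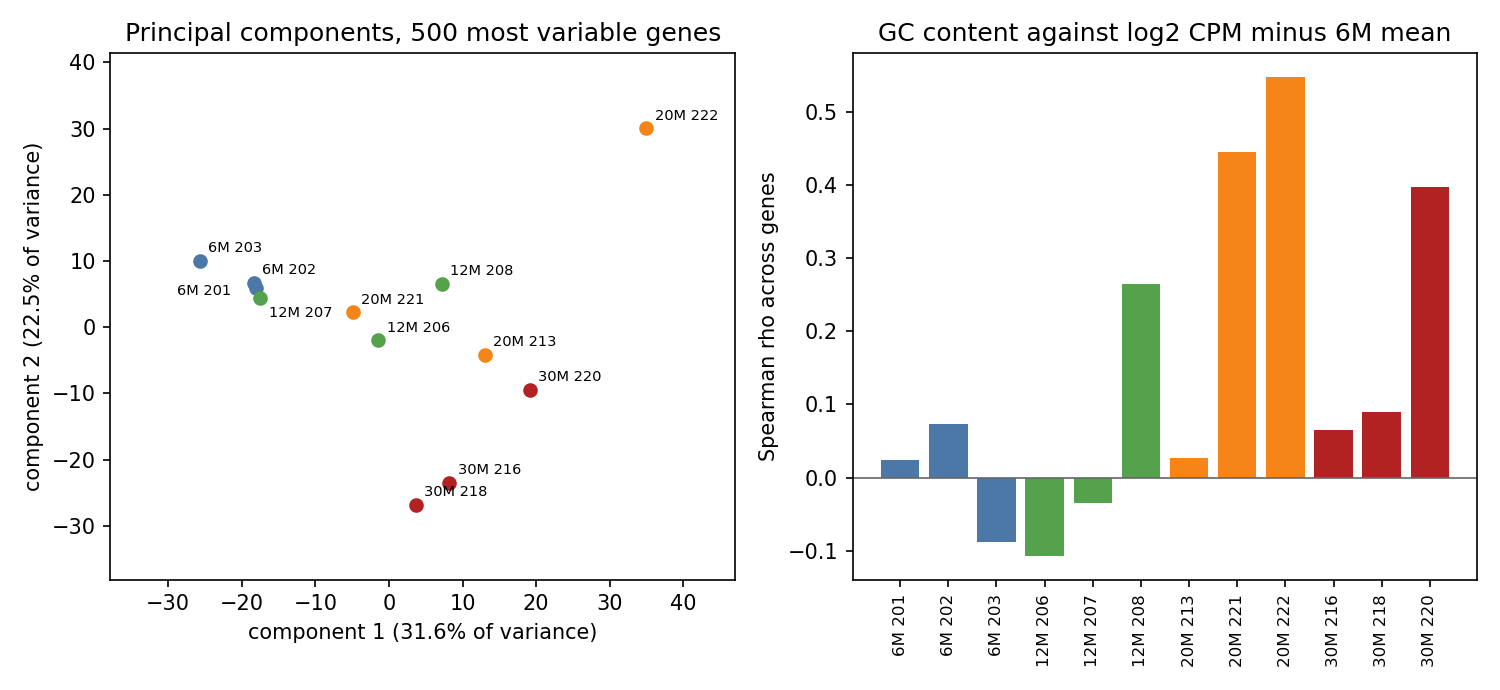
Left, the first 2 principal components of log2 CPM over the 500 most variable genes, 1 point per library coloured by age; right, Spearman rho across genes between GC content and log2 CPM minus the 6M mean, 1 bar per library. The 6M libraries lie at -25.7 to -18.1 on component 1, and rho is 0.397 or more in 20M_221, 20M_222 and 30M_220.

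At 30M, compared with 6M, macrophage, antigen presentation and interferon-stimulated genes were higher and few genes were lower. Of 18407 genes, 361 were called, 356 of them higher and 5 lower, and 288 changed more than 2-fold. Genes of interstitial macrophages, the macrophages of the lung tissue between the air spaces, rose together: 8 of 13 measured genes rose, 0 fell and 5 were not called (11 higher and 0 lower when adjusted over the list alone). The list gave a median 1.63, camera adjusted p = 6.48e-15, and adjusted p = 0.0369 with an estimated correlation. The complement C1q chain gene C1qc (ENSMUSG00000036896, chromosome 4, 136889804 to 136893065) rose from 20.4 ± 3.93 to 84.4 ± 15.6 CPM (log2 fold change 2.05, SE 0.21, adjusted p = 0.000952). The other C1q chains C1qa and C1qb rose from 30.7 ± 2.91 to 96.1 ± 15.2 CPM and from 27.97 ± 1.93 to 104 ± 21.3 CPM. Adgre1, which encodes the F4/80 antigen, rose from 13.9 ± 5.16 to 54.1 ± 6.80 CPM. The largest rise with counts in every age was that of Cd5l (ENSMUSG00000015854, chromosome 3, 87357881 to 87371073), a secreted macrophage protein, from 0.480 ± 0.229 to 58.996 ± 42.8 CPM (log2 fold change 6.92, SE 1.28, adjusted p = 0.0251). Vsig4, a complement receptor of resident macrophages, rose from 0.296 ± 0.179 to 17.3 ± 19.2 CPM (log2 fold change 5.84, SE 1.02, adjusted p = 0.0141). The integrin gene Itgad rose from 0.748 ± 0.531 to 14.3 ± 8.30 CPM (log2 fold change 4.22, SE 0.64, adjusted p = 0.00584). In the lipid-associated macrophage list, 2 of 13 measured genes rose, 0 fell and 11 were not called (5 higher and 0 lower when adjusted over the list alone). The list gave a median 0.22, camera adjusted p = 0.00469, and adjusted p = 0.368 with an estimated correlation. Cd68 rose from 13.96 ± 3.76 to 41.8 ± 7.79 CPM and Trem2 from 3.34 ± 0.402 to 11.6 ± 5.24 CPM. That list's adjusted p was 0.0558 without 6M_201 and 0.0914 without 30M_216. The calls of C1qa, C1qb, C1qc, Adgre1, Cd68 and Itgad held whichever of the 6 libraries was left out (adjusted p up to 0.0487). Those of Cd5l, Vsig4 and Trem2 were lost without 6M_201, 6M_202 or 6M_203 (up to 0.177), and for Cd5l and Trem2 also without 30M_216 or 30M_218. Vsig4 was at 39.1, 10.3 and 2.59 CPM in 30M_216, 30M_218 and 30M_220.

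Antigen presentation and interferon-stimulated genes were higher at 30M. In the MHC class I presentation list, 12 of 16 measured genes rose, 0 fell and 4 were not called (15 higher and 0 lower when adjusted over the list alone). Together these genes had a median 0.99, camera adjusted p = 8.18e-22, and adjusted p = 0.0421 with an estimated correlation. The immunoproteasome subunit Psmb8 (ENSMUSG00000024338, chromosome 17, 34197721 to 34201454) rose from 58.8 ± 6.85 to 138 ± 23.2 CPM (log2 fold change 1.23, SE 0.17, adjusted p = 0.00300). The peptide transporter Tap1 rose from 52.6 ± 14.6 to 125 ± 7.83 CPM (log2 fold change 1.246, SE 0.18, adjusted p = 0.00367). H2-T22 and H2-T23, class I genes with near copies whose counts are uncertain, rose from 92.2 ± 9.53 to 176 ± 35.5 CPM and from 185 ± 23.5 to 361 ± 45.9 CPM. Among interferon-stimulated genes, 9 of 30 measured genes rose, 0 fell and 21 were not called (29 higher and 0 lower when adjusted over the list alone). As a set they had a median 1.42, camera adjusted p = 8.18e-22, and adjusted p = 0.197 with an estimated correlation. The guanylate-binding protein gene Gbp2 rose from 69.1 ± 9.32 to 183 ± 57.9 CPM and the immunity-related GTPase Igtp from 31.9 ± 5.71 to 92.1 ± 15.4 CPM. Oas2 and Oasl2, of the oligoadenylate synthetase family, rose from 12.4 ± 4.46 to 60.5 ± 39.1 CPM and from 40.3 ± 6.48 to 117 ± 58.4 CPM. The list median per library, over the 6M mean, was 2.13, 1.19 and 0.65 (log2) in 30M_216, 30M_218 and 30M_220, the last being the library with the GC trend. For MHC class II presentation, 8 of 12 measured genes rose, 0 fell and 4 were not called (9 higher and 0 lower when adjusted over the list alone). These genes had a median 0.85, camera adjusted p = 8.49e-10, and adjusted p = 0.197 with an estimated correlation. The lysosomal protease Ctss rose from 133 ± 19.6 to 338 ± 93.5 CPM, the thiol reductase Ifi30 from 58.1 ± 6.06 to 102 ± 9.08 CPM and the peptide loading gene H2-DMa from 43.7 ± 8.79 to 80.1 ± 13.99 CPM. Psmb8 and Tap1 were called whichever of the 6 libraries was left out (adjusted p up to 0.0323). Each of the other genes named in this group lost its call without 6M_203 (up to 0.119), H2-T23, Igtp, Oasl2 and H2-DMa also without 6M_202, and Oas2 and Oasl2 also without 6M_201.

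**Figure D2:**
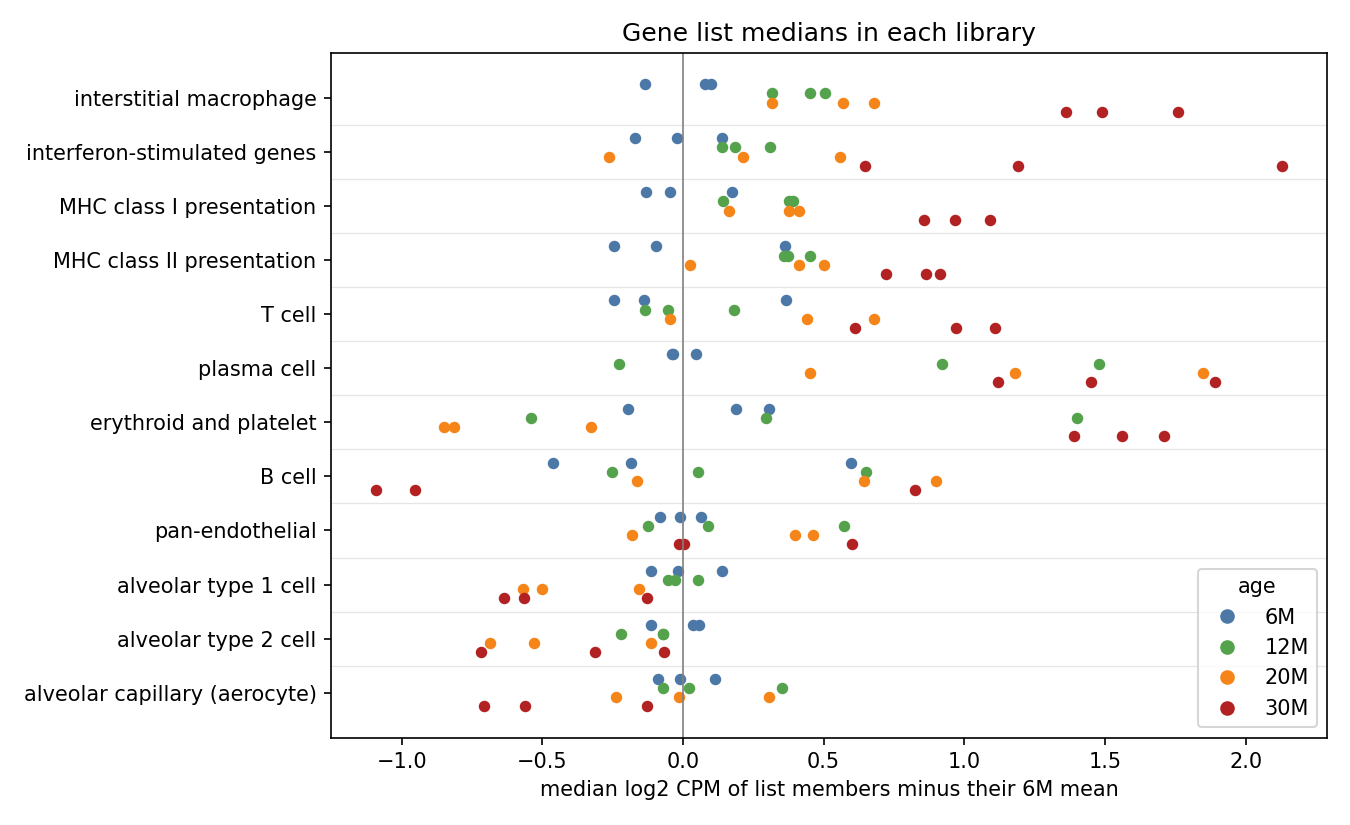
Median log2 CPM of the members of 12 gene lists in each library, minus the members' 6M mean, 1 point per library coloured by age. Interferon-stimulated genes lie at 2.13, 1.19 and 0.646 in the 30M libraries, and alveolar type 2 genes at -0.717 in 30M_220, -0.312 in 30M_218 and -0.0681 in 30M_216.

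Some T cell, cytotoxic lymphocyte and plasma cell genes also rose, while 0 of 15 B cell genes were called. In the T cell list, 3 of 19 measured genes rose, 0 fell and 16 were not called (12 higher and 0 lower when adjusted over the list alone). Across the list there was a median 1.01, camera adjusted p = 5.75e-12, and adjusted p = 0.197 with an estimated correlation. Cd3e and Cd3g, of the T cell receptor complex, rose from 3.61 ± 0.832 to 9.68 ± 3.54 CPM and from 7.63 ± 0.925 to 18.4 ± 4.41 CPM. The adaptor Lat rose from 10.2 ± 1.51 to 22.5 ± 6.41 CPM. In the list of cytotoxic and exhausted lymphocytes, 5 of 17 measured genes rose, 0 fell and 12 were not called (9 higher and 0 lower when adjusted over the list alone). The set had a median 1.38, camera adjusted p = 1.44e-08, and adjusted p = 0.227 with an estimated correlation. The chemokine Ccl5 rose from 14.02 ± 1.68 to 62.4 ± 7.56 CPM and the transcription factor Tbx21 from 1.64 ± 0.275 to 4.28 ± 0.639 CPM. The receptors Pdcd1 and Tigit rose from 0.286 ± 0.187 to 3.79 ± 1.03 CPM and from 0.206 ± 0.150 to 2.05 ± 1.05 CPM. For plasma cells, 3 of 17 measured genes rose, 0 fell and 14 were not called (9 higher and 0 lower when adjusted over the list alone). Its members had a median 2.13, camera adjusted p = 4.65e-09, and adjusted p = 0.197 with an estimated correlation. The immunoglobulin A constant gene Igha (ENSMUSG00000095079, chromosome 12, 113254830 to 113260236) rose from 15.6 ± 5.55 to 73.1 ± 34.6 CPM (log2 fold change 2.22, SE 0.32, adjusted p = 0.00495). The kappa constant gene Igkc rose from 122 ± 20.8 to 1185 ± 316 CPM and the joining chain Jchain from 18.5 ± 1.83 to 228 ± 79.9 CPM. Ighg2c was at 4.78 ± 0.478 and 249.9 ± 163 CPM without a call (adjusted p = 0.0564). The variable segment Igkv6-20 rose from 0.184 ± 0.0350 to 11.1 ± 5.12 CPM, and Ighv14-4 had 1 count at 6M and 127 at 30M, a ratio of 120 (95% exact interval 21.2 to 4780). Both segments belong to families of near copies and are uncertain. Of these lymphoid genes, Igha kept its call whichever of the 6 libraries was left out (adjusted p up to 0.0473). Each of the others called lost it without 6M_203 and without 6M_202, all but Lat and Igkv6-20 without 6M_201, and Igkc, Jchain and Ighv14-4 without any 1 of the 6 (up to 0.244). Of the 30M libraries, 30M_218 mattered also for Lat, Cd3e, Cd3g, Ccl5 and Pdcd1, 30M_216 for Cd3g, Tbx21 and Tigit, and 30M_220 for Cd3e, Tbx21 and Tigit.

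Some chemokine and dendritic cell genes rose as well. In the list of lymphoid chemokines and organisers, 4 of 14 measured genes rose, 0 fell and 10 were not called (6 higher and 0 lower when adjusted over the list alone). The list gave a median 1.20, camera adjusted p = 0.000118, and adjusted p = 0.197 with an estimated correlation. Cxcl13, which attracts B cells, rose from 3.86 ± 2.59 to 35.4 ± 11.8 CPM. Cxcl9 and Cxcl10 rose from 0.465 ± 0.343 to 8.80 ± 2.34 CPM and from 1.60 ± 0.629 to 8.32 ± 5.003 CPM, and the receptor of these 2, Cxcr3, from 2.22 ± 0.671 to 7.31 ± 3.01 CPM. For dendritic cells, 2 of 12 measured genes rose, 0 fell and 10 were not called (6 higher and 0 lower when adjusted over the list alone). The list had a median 0.71, camera adjusted p = 0.000633, and adjusted p = 0.212 with an estimated correlation. Xcr1 rose from 1.72 ± 0.332 to 7.97 ± 4.10 CPM and Flt3 from 2.88 ± 0.676 to 6.82 ± 1.83 CPM. B cell genes fell on balance with none called (median -0.11, camera adjusted p = 0.0302, and adjusted p = 0.766 with an estimated correlation). Cr2 was at 11.3 ± 3.58 and 4.0004 ± 3.76 CPM (adjusted p = 0.378) and Ly6d at 25.5 ± 6.08 and 17.6 ± 4.33 (adjusted p = 0.496). The B cell median was -0.95 and -1.09 in 30M_216 and 30M_218 and 0.83 in 30M_220, the library with the GC trend. The list's adjusted p was 0.459 without 6M_201, 0.448 without 30M_216, 0.466 without 30M_218 and 0.0524 without 12M_208. All 6 called chemokine and dendritic cell genes named here lost the call without 6M_203 (adjusted p up to 0.218) and, save Cxcr3, also without 6M_201. All but Cxcl13 lost it without 6M_202, and Cxcl9 without any 1 of the 6. Of the 30M libraries, 30M_216 and 30M_220 mattered for Cxcl13, 30M_216 and 30M_218 for Cxcl10, 30M_218 for Xcr1, and 30M_218 and 30M_220 for Cxcr3 and Flt3.

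In the erythroid and platelet list, 5 of 11 measured genes rose, 0 fell and 6 were not called (6 higher and 0 lower when adjusted over the list alone). Together these genes had a median 1.62, camera adjusted p = 5.73e-10, and adjusted p = 0.197 with an estimated correlation. The called members named here are platelet genes. Ppbp rose from 15.9 ± 1.88 to 73.6 ± 7.55 CPM (log2 fold change 2.21, SE 0.30, adjusted p = 0.00335) and Pf4 from 11.4 ± 2.86 to 35.05 ± 7.73 CPM. Itga2b rose from 11.2 ± 0.466 to 48.02 ± 16.3 CPM and Gp9 from 1.45 ± 0.232 to 8.23 ± 1.43 CPM. Ppbp, Pf4 and Itga2b were called whichever of the 6 libraries was left out (adjusted p up to 0.0489), and Gp9 lost its call without 6M_202 or 6M_203 (up to 0.0584). Among cell cycle genes, 1 of 28 measured genes rose, 0 fell and 27 were not called (4 higher and 0 lower when adjusted over the list alone). As a list they had a median 0.55, camera adjusted p = 3.47e-09, and adjusted p = 0.248 with an estimated correlation. The proliferation marker Mki67 rose from 12.2 ± 2.01 to 30.5 ± 5.52 CPM (adjusted p = 0.0173), losing its call without 6M_203 (0.129), 6M_201, 6M_202 or 30M_218. Mcm5 was at 7.43 ± 0.976 and 14.1 ± 1.02 CPM (adjusted p = 0.0630). In the NF-kB list, 1 of 18 measured genes rose, 0 fell and 17 were not called (7 higher and 1 lower when adjusted over the list alone). As a set they had a median 0.45, camera adjusted p = 8.33e-05, and adjusted p = 0.197 with an estimated correlation. The chemokine Ccl4 rose from 0.644 ± 0.299 to 5.52 ± 1.43 CPM (adjusted p = 0.00850; 0.0503 without 6M_203), and Saa3 was at 2.54 ± 0.163 and 116 ± 154 CPM (adjusted p = 0.0508). For complement, 2 of 14 measured genes rose, 0 fell and 12 were not called (4 higher and 0 lower when adjusted over the list alone). This list had a median 0.60, camera adjusted p = 0.0146, and adjusted p = 0.361 with an estimated correlation. Properdin Cfp rose from 15.9 ± 2.38 to 59.1 ± 37.8 CPM and C4b, which has a near copy, from 399.8 ± 49.7 to 932 ± 363 CPM. Both lost the call without 6M_201, 6M_202 or 6M_203 (up to 0.205), C4b also without 30M_216 or 30M_218, and the list without 30M_218 (adjusted p = 0.124). Neutrophil genes were higher as a list with none called (median 0.68, camera adjusted p = 0.0471, and adjusted p = 0.736 with an estimated correlation). Ribosomal protein genes were likewise higher (median 0.21, camera adjusted p = 0.00171, and adjusted p = 0.766 with an estimated correlation). Their median per library was 0.313, 0.461 and -0.152 in 30M_216, 30M_218 and 30M_220, and the median log2 fold change was 0.357 with a term for the GC libraries. The neutrophil list kept its call only without 6M_202 or 30M_220, the others giving up to 0.452. The ribosomal list had 0.0619 without 30M_216 and 0.452 without 30M_218.

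Further genes among the largest rises were the eosinophil granule gene Prg2, from 0.131 ± 0.0426 to 5.03 ± 2.27 CPM (log2 fold change 5.15, SE 0.83, adjusted p = 0.00754), and the receptor Fcrl5, from 0.399 ± 0.0940 to 9.87 ± 8.30 CPM. The nuclease Dnase1l3 rose from 0.305 ± 0.320 to 6.32 ± 2.41 CPM. The cytokine Il10 had 2 counts at 6M and 73 at 30M, a ratio of 34.5 (95% exact interval 9.22 to 290). Serpina1b, an antitrypsin gene with near copies whose counts are uncertain, had 0 counts at 6M and 42 at 30M. The lower limit of the 95% exact interval of that ratio was 10.3. Each lost its call without 6M_203 (adjusted p up to 0.169), and all but Serpina1b also without 6M_202. Fcrl5 and Il10 lost it also without 6M_201 and 30M_218 and 30M_220. Among higher genes with a term, innate immune response held 44 of its 351 tested genes against 7.49 by chance (adjusted p = 1.98e-18), inflammatory response 36 of 225 against 4.80. Cellular response to type II interferon held 16 of 73 against 1.56 and platelet aggregation 8 of 23 against 0.491. In all, 112 of 2149 terms passed, in a test that treats genes as independent of one another, which they are not.

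Lower transcripts at 30M were few. Edil3, an integrin ligand (ENSMUSG00000034488, chromosome 13, 88821472 to 89323223), fell from 20.7 ± 2.99 to 7.84 ± 2.08 CPM (log2 fold change -1.39, SE 0.23, adjusted p = 0.00893). The imprinted zinc finger gene Peg3 fell from 15.2 ± 2.04 to 5.59 ± 1.37 CPM (log2 fold change -1.44, SE 0.25, adjusted p = 0.0104). The lysozyme gene Lyz1 of alveolar type 2 cells fell from 592 ± 135 to 235 ± 94.9 CPM (log2 fold change -1.33, SE 0.25, adjusted p = 0.0173). Fibin fell from 69.6 ± 7.89 to 31.2 ± 5.21 CPM (log2 fold change -1.16, SE 0.22, adjusted p = 0.0194). Fam162b, the last of 5, fell from 7.40 ± 1.51 to 3.84 ± 0.437 CPM (log2 fold change -0.94, SE 0.22, adjusted p = 0.0427). Lyz1 has the near copy Lyz2, so its counts are uncertain. Peg3, Lyz1, Fibin and Fam162b lost the call without 6M_202 or 6M_203, and Edil3 without 6M_202 (adjusted p up to 0.263). Lyz1, Fibin and Fam162b lost it also without 30M_218, and Fam162b without 30M_216 or 30M_220. Alveolar type 2 genes fell as a list: 0 of 18 measured genes rose, 1 fell and 17 were not called (0 higher and 1 lower when adjusted over the list alone). Across the list there was a median -0.33, camera adjusted p = 4e-06, and adjusted p = 0.326 with an estimated correlation. Besides Lyz1, Lamp3 was at 768 ± 80.2 and 459.6 ± 146 CPM (adjusted p = 0.206) and the surfactant protein gene Sftpd at 884 ± 146 and 622 ± 191 (adjusted p = 0.410). Alveolar type 1 genes fell too (median -0.37, camera adjusted p = 5.72e-07, and adjusted p = 0.299 with an estimated correlation), with 0 of 14 called. Akap5 was at 627 ± 14.5 and 342 ± 45.5 CPM (adjusted p = 0.163) and Hopx at 1311 ± 201.1 and 845 ± 211 (adjusted p = 0.267). The type 2 median was -0.717 in 30M_220, with the GC trend, -0.687 and -0.528 in 20M_221 and 20M_222, which share that trend, and -0.0681 and -0.312 in 30M_216 and 30M_218. Genes of the alveolar capillary cell called aerocyte, which include Fibin, also fell (median -0.33, camera adjusted p = 0.000125, and adjusted p = 0.326 with an estimated correlation), with Apln at 36.1 ± 7.79 and 15.5 ± 3.28 CPM (adjusted p = 0.0529).

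The lists that follow passed the threshold with no member called. Lower were ciliated cell (median -0.25, camera adjusted p = 0.000228, and adjusted p = 0.326 with an estimated correlation) and club cell genes (median -0.24, camera adjusted p = 0.00946, and adjusted p = 0.604 with an estimated correlation). Dnah5 was at 76.9 ± 4.47 and 56.2 ± 6.05 CPM (adjusted p = 0.159) and Scgb3a1 at 334 ± 65.03 and 158 ± 15.97 (adjusted p = 0.0738). Cytosolic heat shock genes were lower (median -0.37, camera adjusted p = 0.0146, and adjusted p = 0.745 with an estimated correlation), with Hsp90aa1 at 1051 ± 339.6 and 661 ± 170.1 CPM. Immediate early genes were lower too (median -0.47, camera adjusted p = 0.0146, and adjusted p = 0.718 with an estimated correlation), with Egr1 at 74.6 ± 59.98 and 25.1 ± 4.30. Basement membrane genes followed (median -0.09, camera adjusted p = 0.0156, and adjusted p = 0.736 with an estimated correlation). Their median per library was -0.235, -0.517 and 0.303 in 30M_216, 30M_218 and 30M_220, and the median log2 fold change was -0.303 with a term for the GC libraries. In 30M_216 the club and neuroendocrine medians were 0.0149 and 0.0184. Neuroendocrine genes were lower as well (median -0.57, camera adjusted p = 0.0177, and adjusted p = 0.197 with an estimated correlation), with Calca at 2.08 ± 0.274 and 0.925 ± 0.115. Alveolar fibroblast genes were the last (median -0.24, camera adjusted p = 0.0397, and adjusted p = 0.197 with an estimated correlation), with Pdgfra at 270.4 ± 12.8 and 201.4 ± 38.1. Of these 7 lists only that of ciliated cells kept its call whichever of the 6 libraries was left out. The club cell list lost it without 30M_218 (adjusted p = 0.0963), heat shock without 6M_202 and 6M_203 and 30M_218 and 30M_220 (0.0736 to 0.141). The immediate early list lost it without 6M_201 (0.494) and 30M_218 (0.101), and basement membrane without 30M_216 (0.0619) and 30M_218 (0.336). Neuroendocrine lost it without 30M_220 (0.0613), and alveolar fibroblast without 6M_201 and 6M_202 and 30M_216 and 30M_220 (0.0574 to 0.193).

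The senescence and secretory factor list did not pass (camera adjusted p = 0.0563; adjusted p = 0.326 with an estimated correlation), though it had 0.0447 without 6M_202 and 0.016 without 30M_220. Cdkn2a, which encodes the cell cycle inhibitor p16, was at 0.485 ± 0.309 and 1.15 ± 0.517 CPM (log2 fold change 1.26, SE 0.54, adjusted p = 0.377). Cdkn1a, which encodes p21, was at 127 ± 60.01 and 102 ± 39.001 (log2 fold change -0.31, SE 0.57, adjusted p = 0.919). Mmp13 stood at 0.915 ± 0.437 and 9.12 ± 11.05 CPM (adjusted p = 0.0602) and Ccl8 at 2.18 ± 1.09 and 16.99 ± 5.83 (adjusted p = 0.0663). Neither p53 targets (camera adjusted p = 0.816) nor alveolar macrophage genes (0.858) passed. Pmaip1, of the p53 list, rose from 16.9 ± 2.64 to 31.1 ± 1.94 CPM (adjusted p = 0.0374, lost without any 1 of the 6 libraries). Marco was at 10.2 ± 3.21 and 28.4 ± 8.88 CPM (adjusted p = 0.0534). Fibrillar collagen and matrix genes gave 0.183, with 0.0152 without 30M_220 and Postn at 230.1 ± 23.5 and 174 ± 25.96 CPM. Pan-endothelial genes gave 0.126, with 0.0189 without 30M_216 and Pecam1 at 488 ± 11.9 and 634 ± 150.3. The remaining lists that did not pass gave camera adjusted p = 0.0958 to 0.994.

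In all, 27 of 56 lists passed at 30M against 6M (16 up, 11 down). Of these, MHC class I presentation and interstitial macrophage passed with an estimated correlation. By fry 12 passed, 11 up and 1 down. Of the lower lists, fry gave alveolar type 1 adjusted p = 0.0824, alveolar type 2, aerocyte and ciliated 0.114 each, and B cell 0.688. The number of called genes was 217, 121 and 69 without 6M_201, 6M_202 and 6M_203, and 214 without 30M_218; 67 of the 361 were called whichever of the 6 libraries was left out, and all 361 kept their sign. Of the 66 called genes named for this comparison here and in the closing section, 38, 25 and 17 kept their call without 6M_201, 6M_202 and 6M_203, and 49, 40 and 52 without 30M_216, 30M_218 and 30M_220. DESeq2 called 753 genes (671 higher, 82 lower) and limma voom 600, and 131 were called at 30M against 12M, with 22 of those 66 kept. Between the libraries of the 2 ages, 3415 genes (18.6%) had no overlap, against 10% by chance. That share was 12.1% at 12M against 6M and 15% at 20M against 12M, where no gene was called. It was 15.4% at 20M against 6M and 10.8% at 30M against 20M. Genes are not independent of one another, so a share above 10% does not by itself show a change with age.

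**Figure D3:**
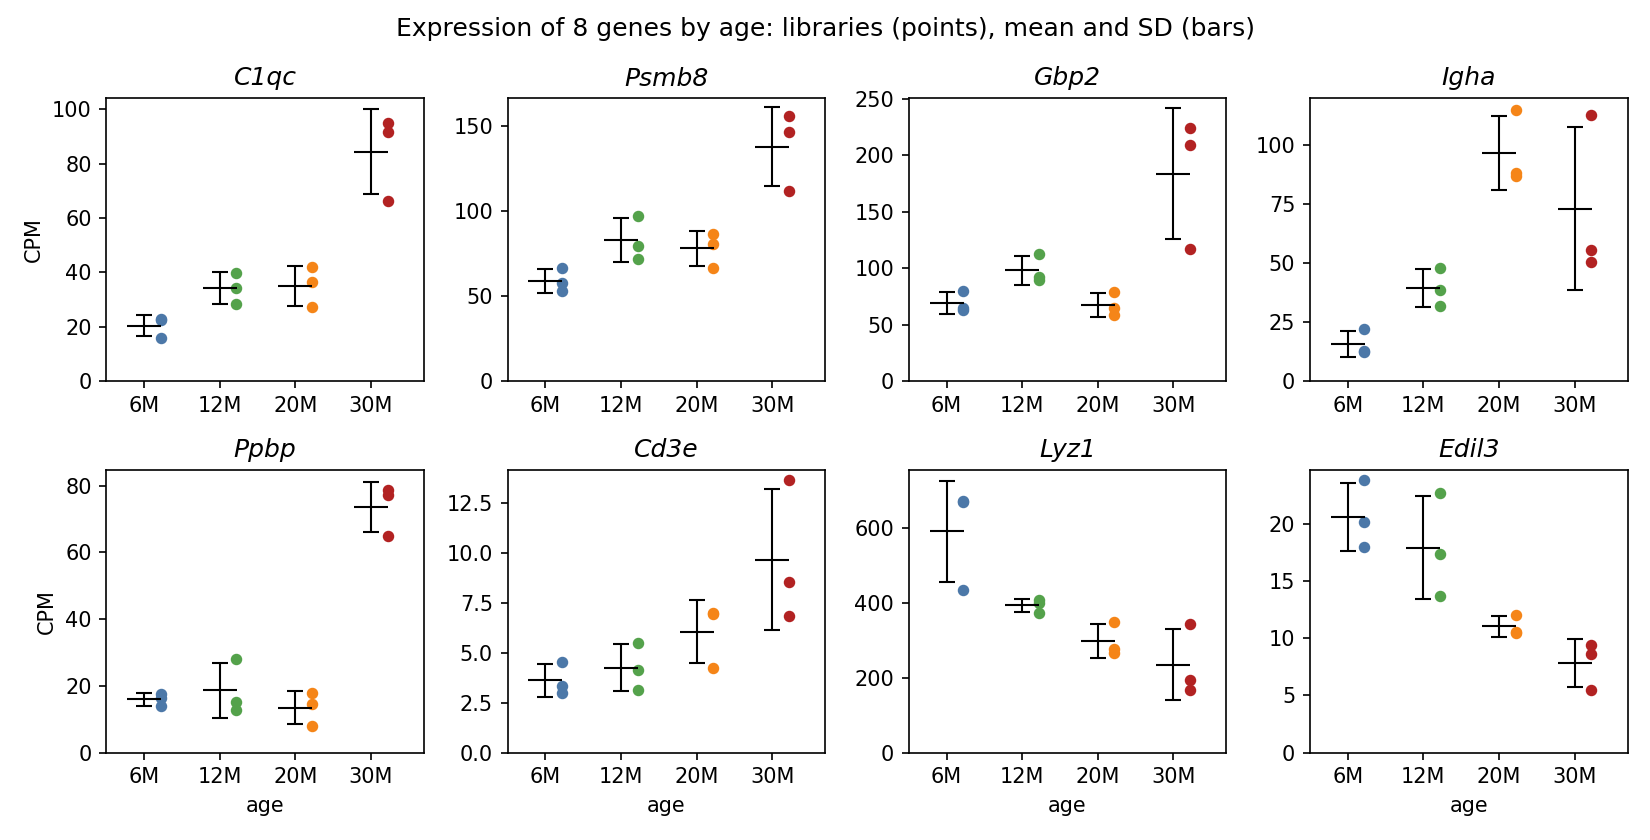
CPM of 8 genes at each age, 1 point per library, with the mean and SD of 3 libraries beside the points. C1qc goes from 20.4 CPM at 6M to 84.4 at 30M and Lyz1 from 592 to 235.

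Expression was also fitted as a slope on age in months. A late step gives a slope too: C1qc was at 20.4 ± 3.93, 34.2 ± 5.78, 35.1 ± 7.41 and 84.4 ± 15.6 CPM at 6M, 12M, 20M and 30M. With predicted genes left out, the 5 rises with the smallest p were these. The metal transporter Slc11a1 rose by 0.10 log2 units per month (SE 0.0107, adjusted p = 0.00134), the lysosomal nuclease Pld4 by 0.09 (SE 0.00975). The integrin partner Fermt3 rose by 0.07 (SE 0.00805), the integrin chain Itgb2 by 0.06 (SE 0.00764), and C1qc by 0.08 (SE 0.00957). The falls with the smallest adjusted p were Edil3 (-0.06 per month, SE 0.00902, adjusted p = 0.00233), Fibin (-0.05), Lyz1 (-0.05), Peg3 (-0.05) and Fam162b (-0.04, adjusted p = 0.0125). In total 494 genes had a slope, 461 upward and 33 downward. Of these 10 named genes Fam162b lost its call without 6M_203 or 30M_220 (adjusted p up to 0.0577), and the other 9 kept theirs whichever of the 12 libraries was left out. Lists with upward slopes, 14 of 56, included MHC class I presentation (12 of 16 called), interferon-stimulated genes (13 of 30), interstitial macrophage (9 of 13) and T cell (6 of 19), with camera adjusted p = 2.97e-18, 2.97e-18, 9.6e-13 and 7.4e-14. With an estimated correlation these had adjusted p = 0.104, 0.275, 0.0962 and 0.264. Downward lists, 11 of 56, included alveolar type 1 (camera adjusted p = 1.26e-08; 0 called, 10 lower when adjusted over the list alone), alveolar type 2 (2.09e-07; 1 and 2) and aerocyte (4.7e-05; 2 and 5), where adjusted p = 0.275, 0.281 and 0.275 with an estimated correlation. Fry passed 13 lists (10 up, 3 down), but not alveolar type 2 or aerocyte (adjusted p = 0.0715 each). The count of genes was 234 without 6M_203, 288 without 30M_218 and 254 without 30M_220. It was 254 with age as log2 of months and 900 with DESeq2. The joint test over all ages called 205 genes, with 106 and 96 without 6M_202 and 6M_203, 85 and 67 without 30M_216 and 30M_218, 316 with no filter, 788 with DESeq2 and 1590 with voom.

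Between 20M and 30M, macrophage, interferon-stimulated, class I and platelet genes were higher at 30M. All 39 called genes were higher, and 1636 had an unadjusted p under 0.05. Vsig4 rose from 0.317 ± 0.259 to 17.3 ± 19.2 CPM (log2 fold change 5.76, SE 1.01, adjusted p = 0.0494). Trim10, a gene of red cell precursors, rose from 0.195 ± 0.157 to 2.16 ± 0.825 CPM (log2 fold change 3.44, SE 0.60, adjusted p = 0.0378). Itgad rose from 1.35 ± 0.702 to 14.3 ± 8.30 CPM and Ms4a6d from 6.94 ± 3.71 to 40.8 ± 21.5 CPM. Ppbp rose from 13.4 ± 4.98 to 73.6 ± 7.55 CPM (log2 fold change 2.45, SE 0.31, adjusted p = 0.0185). Trim10 had 8 counts over the 20M libraries, so its fold is imprecise. Among interstitial macrophage genes, 3 of 13 measured genes rose, 0 fell and 10 were not called (7 higher and 0 lower when adjusted over the list alone). They had a median 1.10, camera adjusted p = 3.61e-11, and adjusted p = 0.0628 with an estimated correlation. C1qb rose from 37.8 ± 9.40 to 104 ± 21.3 CPM, Adgre1 from 18.2 ± 1.42 to 54.1 ± 6.80 CPM and C1qc from 35.1 ± 7.41 to 84.4 ± 15.6 CPM. Among interferon-stimulated genes, 3 of 30 measured genes rose, 0 fell and 27 were not called (28 higher and 0 lower when adjusted over the list alone). Here the list had a median 1.39, camera adjusted p = 4.2e-22, and adjusted p = 0.337 with an estimated correlation and 0.119 by fry. Gbp2 rose from 67.4 ± 10.3 to 183 ± 57.9 CPM, Igtp from 33.96 ± 8.12 to 92.1 ± 15.4 CPM and Iigp1 from 30.2 ± 10.4 to 94.996 ± 12.9 CPM. The erythroid and platelet list rose with 2 of 11 called, Ppbp and Pf4 (from 10.9 ± 2.73 to 35.05 ± 7.73 CPM). It had a median 1.90, camera adjusted p = 4.86e-19, and adjusted p = 0.0628 with an estimated correlation. Its median over the 6M mean was -0.327, -0.814 and -0.85 in 20M_213, 20M_221 and 20M_222. In 30M_216, 30M_218 and 30M_220 it was 1.39, 1.71 and 1.56. More blood left in the 30M lungs was not tested as a cause of the rises from 20M. The MHC class I list rose with 1 of 16, H2-T22 (from 99.3 ± 3.43 to 176 ± 35.5 CPM; median 0.68, camera adjusted p = 7.45e-17, and adjusted p = 0.0628 with an estimated correlation). Ciliated cell genes fell (median -0.38, camera adjusted p = 2.41e-08, and adjusted p = 0.315 with an estimated correlation), with Dnah5 at 81.4 ± 12.9 and 56.2 ± 6.05 CPM (adjusted p = 0.181). B cell genes fell too (median -0.60, camera adjusted p = 1.5e-05, and adjusted p = 0.557 with an estimated correlation), with Ly6d at 36.1 ± 12.6 and 17.6 ± 4.33 (adjusted p = 0.180). The B cell median over the 6M mean was 0.644, 0.901 and -0.162 in 20M_213, 20M_221 and 20M_222. It was -0.951 and -1.09 in 30M_216 and 30M_218 but 0.826 in 30M_220, so the 30M libraries disagree.

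Skeletal muscle genes fell from 20M to 30M as a list (median -5.02, camera adjusted p = 0.0162, and adjusted p = 0.672 with an estimated correlation), with Acta1 at 346 ± 599.7 and 0.874 ± 1.09 CPM (adjusted p = 0.342). Their median per library over the 6M mean was 7.02 in 20M_222 against 0.146 and 0.113 in the other 20M libraries, and without that replicate the list turned to higher at 30M (adjusted p = 0.595). Of 56 lists 23 passed between 20M and 30M (16 up, 7 down), 0 with an estimated correlation and 3 by fry. Of the 3 libraries with a steep GC trend 2 are at 20M and 1 at 30M. With a term for them 36 genes were called, 8 of the 13 named here among them, and with each GC trend removed 52, with all 13. Leaving them out gave 0, but this leaves 1 library at 20M and 2 at 30M and so says little about the trend. The count was also 0 without 20M_221, 30M_216 or 30M_218, 3 without 20M_222, and 78 without 30M_220. A fit of these 2 ages alone gave 0, and all 13 called genes named here lost their call in it, as they did without 20M_221, 30M_216 or 30M_218 (adjusted p up to 0.276 with 1 library out). Without 12M_208, a library of neither age, 6 of the 13 kept their call. No filter gave 77, DESeq2 319, and voom 187 higher and 29 lower.

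At 20M, plasma cell genes were higher than at 6M and alveolar genes lower as lists. Igha rose from 15.6 ± 5.55 to 96.7 ± 15.7 CPM (log2 fold change 2.63, SE 0.33, adjusted p = 0.0263). The 2 other called genes are predicted genes on chromosome 1, named here after their values were seen. C130026I21Rik rose from 3.09 ± 1.40 to 17.2 ± 2.47 CPM (log2 fold change 2.47, SE 0.27, adjusted p = 0.00747). Gm16028, annotated as antisense within the span of C130026I21Rik and so uncertain, rose from 0.447 ± 0.108 to 3.62 ± 0.884 CPM (log2 fold change 2.99, SE 0.41, adjusted p = 0.0318). In the plasma cell list, 1 of 17 measured genes rose, 0 fell and 16 were not called (6 higher and 0 lower when adjusted over the list alone). The plasma cell genes had a median 1.24, camera adjusted p = 4.04e-08, and adjusted p = 0.573 with an estimated correlation. Jchain was at 18.5 ± 1.83 and 243 ± 158 CPM (adjusted p = 0.495) and Igkc at 122 ± 20.8 and 1134 ± 617 (adjusted p = 0.530). Alveolar type 2 genes fell as a list (median -0.48, camera adjusted p = 4.04e-08, and adjusted p = 0.573 with an estimated correlation), with none called. Lamp3 was at 768 ± 80.2 and 451 ± 149 CPM (adjusted p = 0.638) and Lyz1 at 592 ± 135 and 298 ± 45.4 (adjusted p = 0.574). Alveolar type 1 genes did likewise (median -0.39, camera adjusted p = 4.04e-08, and adjusted p = 0.573 with an estimated correlation), Cav1 being at 1388 ± 94.3 and 972 ± 128 CPM (adjusted p = 0.638). The type 1 median was -0.570 and -0.501 in the 20M replicates with a GC trend, 20M_221 and 20M_222, and -0.157 in 20M_213. Interstitial macrophage genes (median 0.53, camera adjusted p = 0.000345, and adjusted p = 0.573 with an estimated correlation) and MHC class I genes (median 0.32, camera adjusted p = 6.25e-05, and adjusted p = 0.573 with an estimated correlation) rose as lists with none called. C1qc was at 35.1 ± 7.41 CPM (adjusted p = 0.638) and Tap2 at 125 ± 15.7 against 87.6 ± 7.30 (adjusted p = 0.584). Skeletal muscle genes gave camera adjusted p = 0.061 (0.022 and 0.000391 without 20M_213 and 20M_221, 0.045 without 6M_202, 0.804 without 20M_222).

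The 3 called genes were among 1436 with an unadjusted p under 0.05, and 16 of 56 lists passed (8 up, 8 down), 0 with an estimated correlation and 0 by fry. C130026I21Rik kept its call without any 1 library except 6M_202 and 6M_203 (adjusted p up to 0.0731), Igha kept it only without 6M_202 (0.0482 to 0.308), and Gm16028 lost it without any of the 6 (0.0535 to 0.308). The count was 0 without 6M_203, 1 without 6M_201 and 6M_202, 20M_213 and 20M_222 or 12M_208, and 2 without 20M_221. A fit of these 2 ages alone also called 3 genes but only Igha of those named, C130026I21Rik and Gm16028 having adjusted p = 0.0549 and 0.0803. With no filter Igha was lost (0.0857), with a term for the GC libraries Gm16028 (0.105), and without those libraries, which leaves 1 at 20M, all 3 (0.0567 to 0.167). The count was 56 with DESeq2 and 609 with voom (268 higher, 341 lower).

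At 12M against 6M, no single gene was called, while 18 lists were higher and 4 lower. MHC class I genes rose as a list (median 0.33, camera adjusted p = 1.06e-06, and adjusted p = 0.523 with an estimated correlation). Psmb8 was at 58.8 ± 6.85 and 82.7 ± 12.99 CPM (adjusted p = 0.988) and B2m at 825 ± 89.7 and 1149 ± 159. MHC class II genes did so too (median 0.36, camera adjusted p = 3.46e-05, and adjusted p = 0.523 with an estimated correlation), with H2-Ab1 at 278 ± 55.997 and 401 ± 62.6 CPM. For plasma cells (median 0.84, camera adjusted p = 4.5e-05, and adjusted p = 0.551 with an estimated correlation), 5 of 17 genes were higher when adjusted over the list alone. Jchain was at 18.5 ± 1.83 and 207.9 ± 167 CPM, Igha at 15.6 ± 5.55 and 39.5 ± 8.15 and Igkc at 122 ± 20.8 and 823 ± 725 (each adjusted p = 0.988). Interstitial macrophage genes (median 0.39, camera adjusted p = 8.27e-05, and adjusted p = 0.523 with an estimated correlation), lymphoid chemokines (median 0.66, camera adjusted p = 2.18e-05, and adjusted p = 0.523 with an estimated correlation) and ribosomal protein genes (median 0.25, camera adjusted p = 2.15e-06, and adjusted p = 0.773 with an estimated correlation) rose as lists. C1qc was at 34.2 ± 5.78 CPM, Cxcl9 at 3.06 ± 1.72 against 0.465 ± 0.343 and Rplp2 at 321 ± 88.1 against 229 ± 30.8. The plasma cell median per library was 0.921, -0.227 and 1.48 in 12M_206, 12M_207 and 12M_208. The ribosomal median was 0.043, 0.149 and 0.491 in these, so it was highest in 12M_208, which stood apart. In edgeR 0 of 18407 genes were called with 662 at an unadjusted p under 0.05, where 920.4 would fall by chance, against 9 in DESeq2 and 1 in edgeR without 6M_201 or 12M_207. The lower lists were alveolar macrophage (median -0.26, camera adjusted p = 0.00161; up to 0.0347 with 1 library out), alveolar type 2 (-0.14, 0.0432), cholesterol synthesis (-0.12, 0.0125) and the sex-linked genes (-0.29, 0.0432). Type 2 lost its call without 6M_202 or 6M_203 or 12M_206 or 12M_207 (up to 0.338) and cholesterol synthesis without 6M_201 or 12M_206 (up to 0.125). The sex-linked genes lost it without 6M_201 or 6M_203 or 12M_208 (up to 0.698), with the GC trend removed (0.109) and without the 3 GC libraries (0.0731). Of 56 lists 22 passed (18 up, 4 down), 14 without 12M_208, 0 with an estimated correlation and 0 by fry.

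Between 12M and 20M no gene was called in edgeR, with 2062 at an unadjusted p under 0.05 and 9 called by DESeq2. Without overlap between the libraries of the 2 ages were 2763 genes (15%), against 10% by chance, which does not by itself show a change. Igha, at 39.5 ± 8.15 and 96.7 ± 15.7 CPM, had a log2 fold change of 1.29 (SE 0.31, adjusted p = 0.429) and was picked here after its values were seen.

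Changes at 20M and at 30M against the same 6M libraries were compared. All 3 genes called at 20M were called at 30M, and 96 genes were higher in both at an unadjusted p under 0.01. Simulated unchanged groups against shared 6M libraries, which were simulated too, gave 17.4, and independent lists would give 8.67. Log2 fold changes correlated across 17039 genes at r = 0.570 against 0.510 in the simulation, and their covariance was 0.162 against 0.0598, a difference of 0.103. With 3 libraries at 6M the controls could not be split, so part of the excess may come from them. The simulated counts also held no GC trend, whereas 20M_221, 20M_222 and 30M_220 share a steep one. Part of the excess may come from that trend, so it cannot be read as shared change with age alone. The changes from 6M to 12M and from 20M to 30M, which share no library, correlated at r = 0.0895 across genes, against 0.0079 in the simulation. Their covariance was 0.0167 against 0.000923. At an unadjusted p under 0.01, 8 genes were higher in both against 1.55 in the simulation, and 1 was lower in both against 1.85.

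**Figure D4:**
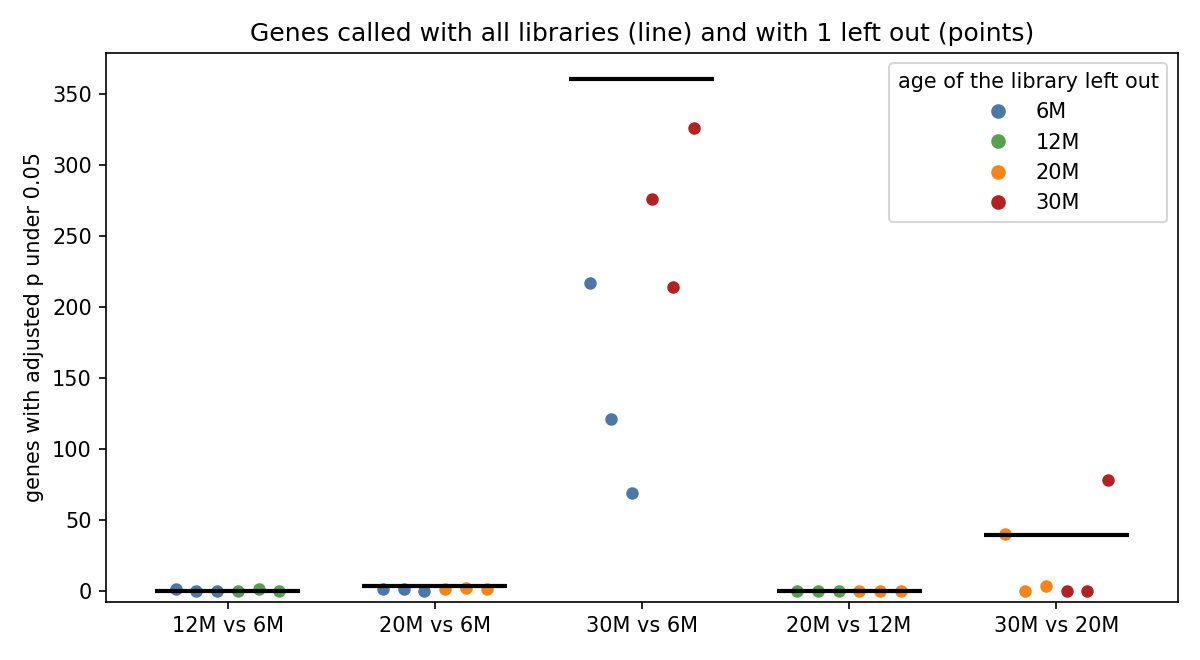
Number of genes with adjusted p under 0.05 in each comparison, with all 12 libraries (black line) and with 1 library of the compared ages left out (points, coloured by that library's age). For 30M against 6M the count is 361 with all libraries and runs from 69 to 326 with 1 left out.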

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

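The fits with each GC trend removed, with a term for the 3 libraries with a steep trend, without those 3, without 12M_208 where 12M was not compared and without 20M_222 where 20M was not compared were chosen after the data were seen, the others before. No paired analysis was possible because no replicate number occurs at more than 1 age. The cause of the changes below was not tested. Genes called at 12M against 6M went from 0 to 9 with DESeq2, and 0 to 1 when 1 library was left out. At 20M against 6M, 3 became 56 with DESeq2, 609 with voom and 1 without 12M_208, and 0 to 2 with 1 library out. At 30M against 6M, 361 became 753 with DESeq2, 600 with voom and 131 with 12M as reference, and 69 to 326 with 1 library of these ages out (415 without 12M_208). At 20M against 12M, 0 became 9 with DESeq2 and stayed 0 with 1 library out. At 30M against 20M, 39 became 77 with no filter, 319 with DESeq2, about 2.2e+02 with voom (187 higher, 29 lower), 0 with these 2 ages alone and 0 without the 3 GC libraries (1 library then being left at 20M), and 0 to 78 with 1 library out. Genes differing among any ages went from 205 to 316 with no filter, 788 with DESeq2 and 1590 with voom, and 67 to 285 with 1 library out. Trend genes went from 494 to 900 with DESeq2 and 254 with log2 of months, and 234 to 608 with 1 library out. Lists past the threshold fell to 0 with an estimated correlation at 12M, 20M, 30M against 20M and in the trend, from 22, 16, 23 and 25, and to 2 from 27 at 30M against 6M. By fry they were 0, 0, 3, 13 and 12. With 1 library out they were 14 to 24, 11 to 21, 20 to 26, 23 to 31 and 20 to 30. Genes shared by 20M and 30M went from 3 to 96 at an unadjusted p under 0.01, and the share of component 1 from 31.6% to 23.6% with 2000 genes.

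Of the named results that changed sign, none had been called except the skeletal muscle list from 20M to 30M. Against 12M the log2 fold changes at 30M were -0.47 for Cdkn2a, -0.073 for Pecam1, -1.04 for Alb, 0.27 for Kdm5d and 0.32 for Eif2s3y. With the GC trend removed they were 0.054 for Kdm5d and 0.073 for Eif2s3y, which had 0.00445 with the GC term. With 1 library out, Cdkn1a ran from -0.64 to 0.046 and Xist from -0.71 to 0.015, both highest without 6M_203. Kdm5d ran from -0.22 to 0.041, above 0 without 6M_201 or 30M_216 (0.025). For Acta1 30M vs 20M the log2 fold change was 0.64 without the 3 GC libraries and ran from -10.41 to 2.33, highest without 20M_222, where the muscle list had adjusted p = 0.595 (8.09e-05 without 20M_221). At 30M against 6M the alveolar macrophage list turned with adjusted p = 1 by fry, 0.752 without 6M_202 and 0.77 without 30M_218 (0.526 to 0.837 with 1 library out). The p53 target list turned with 0.855 without 6M_202 (from 0.256). Of the 66 called genes named at 30M against 6M, 66 stayed called with DESeq2's size factors, 66 with DESeq2, 65 with voom, 52 with no filter, 60 with the GC term, 22 with 12M as reference and 50 without the 3 GC libraries. With these 2 ages alone 51 of 64 measured stayed called. With 3 libraries per age, 2-fold changes were found in 47.8% of simulated cases, so a gene without a call may still have changed.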

Other observations

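Apart from the test of the GC trend on alveolar genes, which was set before its result, the tests and genes in this part were chosen after the values were seen. Of other leukocyte genes picked from their values, some were called at 30M against 6M and others were not. Treml4 rose from 3.997 ± 1.97 to 23.5 ± 5.74 CPM (log2 fold change 2.55, SE 0.40, adjusted p = 0.00677), Spn from 21.5 ± 7.54 to 86.8 ± 24.9 CPM (log2 fold change 2.01, SE 0.29, adjusted p = 0.00465) and Itgal from 44.7 ± 13.6 to 129.9 ± 38.2 CPM (log2 fold change 1.54, SE 0.23, adjusted p = 0.00550). Ccr2 and Ly6c2 were at 40.8 ± 18.8 and 18.9 ± 5.15 CPM at 6M and 154 ± 75.7 and 109 ± 103 at 30M, changes of 3.76-fold and 5.76-fold without a call (adjusted p = 0.133 and 0.0757). No list of monocyte genes was tested. Spic, a transcription factor of iron-recycling macrophages, rose from 1.20 ± 0.319 to 6.27 ± 1.37 CPM (log2 fold change 2.37, SE 0.47, adjusted p = 0.0210). Clec4f, a marker of liver macrophages, had 0 counts at 6M and 12M and stood at 54.5 CPM in 30M_216, 1.64 in 30M_218 and 3.88 in 30M_220 (adjusted p = 0.255), while Alb, the most abundant liver transcript, was at 1.24 ± 1.07 CPM at 30M. Treml4 lost its call without 6M_203 (adjusted p = 0.0542), and Spic without 6M_201, 6M_202, 6M_203 or 30M_218 (up to 0.15).

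A stretch of chromosome 1 held several rising genes. C130026I21Rik (ENSMUSG00000052477, chromosome 1, 84992690 to 85270566) stood at 3.09 ± 1.40, 9.39 ± 1.54, 17.2 ± 2.47 and 24.4 ± 1.13 CPM at 6M, 12M, 20M and 30M (30M against 6M log2 fold change 2.97, SE 0.27, adjusted p = 0.000952). Nearby, AC147806.2 (start 85526602) rose from 0.370 ± 0.126 to 7.76 ± 4.39 CPM, and the interferon-responsive genes Sp110 (start 85576899), Sp140 and Sp100 rose from 38.2 ± 4.37 to 69.5 ± 5.89 CPM, from 22.8 ± 3.59 to 40.9 ± 4.88 CPM and from 90.2 ± 15.2 to 158 ± 32.7 CPM (adjusted p = 0.0242, 0.0307 and 0.0466). C130026I21Rik and AC147806.2 were called whichever of the 6 libraries was left out (up to 0.0122). Sp110 lost its call without 6M_202 or 6M_203 or 30M_216, and Sp140 and Sp100 also without 6M_201 or 30M_218 (up to 0.264). Counts of repeated copies in this region are uncertain. Immunoglobulin and T cell receptor segments took 0.0564% ± 0.0131 of counts at 6M and 0.385% ± 0.0488 at 30M (SD, n = 3). Between these an exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 can give. The share was 0.249% ± 0.197 at 12M and 0.407% ± 0.204 at 20M, so a high share was not particular to 30M. In 12M_208 the segment Igkv3-2 took 49.8% of kappa variable segment counts (95% exact interval 48.6 to 51.1), against 16.3% and 20.8% in the other 12M libraries. It also led in other ages, with 25%, 28.1% and 35.6% in 20M_222, 30M_216 and 30M_218. In 6M_201, 6M_202, 20M_213 and 30M_220 another segment led.

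Interstitial macrophage, interferon-stimulated and MHC class I genes rose at 30M as lists, with 8 of 13, 9 of 30 and 12 of 16 called. A GC trend as the whole cause is argued against, since with the trend removed all 29 called members stayed called (median log2 fold change 1.23, against 1.30 before). A lower share of other cell types would raise all remaining types alike, and the pan-endothelial median was 0.193 (SE over genes 0.0663) and the B cell median -0.107 (SE 0.163), under the 1.30 of these lists (SE 0.106). The lists exceeded pan-endothelial genes by 1.62, 1.11 and 0.233 in 30M_216, 30M_218 and 30M_220 (SD 0.134 at 6M) and B cell genes by 2.56, 2.20 and 0.00552 (SD 0.409). A lower share thus stays open, since 30M_220 did not set the lists apart from B cell genes and had the smallest gap to pan-endothelial genes. More blood left in the lungs stays open. The 6 red cell genes measured were higher too (median log2 fold change 0.797, against 1.30 for the lists). The lists exceeded red cell genes by 0.346 log2 units on average, within the 0.55 SD of that difference at 6M. It was 0.898, 0.474 and -0.334 in 30M_216, 30M_218 and 30M_220, so 30M_216 lay above that SD, though within 2 SD. Age itself, whether as more cells or more expression per cell, may also explain the rise and was not separated from these here.

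Skeletal muscle and squamous epithelial genes were high in 20M_222. There 8 of the 11 muscle genes were at 10 CPM or more and over 10 times the highest other library in CPM without TMM scaling, as Myh1 at 955.3 against at most 0.576 and Ckm at 535.6 against at most 34.9. This describes the pattern and does not test its origin, so neighbouring tissue carried along with that lung and other causes within it cannot be told apart. The muscle median over the 6M mean was 0.146 in 20M_213 and 0.113 in 20M_221, against 7.02 in 20M_222, so the 20M libraries did not share the pattern. As 20M_222 was picked from these values, this too describes the pattern.

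Alveolar type 1 and type 2 genes were lower at 30M as lists, with 0 of 14 and 1 of 18 called. They had adjusted p = 0.299 and 0.326 with an estimated correlation, and 0.0824 and 0.114 by fry. With the GC trend removed their median log2 fold change was -0.366 (SE over genes 0.0546, 32 genes), against -0.365 before. That argues against the dependence on GC content itself as the cause, but not against other differences of the 3 GC libraries. Spearman rho of expression over the 6M mean with gene length was 0.117, 0.107 and 0.136 in 20M_221, 20M_222 and 30M_220. It was -0.277, -0.197 and -0.287 in 20M_213, 30M_216 and 30M_218, but 0.135 in 6M_201. Gene length as a cause was not tested. Without the 3 GC libraries the median fold change was -0.27. The type 2 median was -0.687, -0.528 and -0.717 in 20M_221, 20M_222 and 30M_220. In 20M_213, 30M_216 and 30M_218 it was -0.114, -0.0681 and -0.312, though the type 1 median was -0.567 in 30M_218. Dilution by immune cells would lower all resident types alike. The pan-endothelial median lay 0.559 above that of these lists (SE over genes 0.0897), and 0.304 above without 30M_220. Per library it lay 0.0863, 0.392 and 1.26 above in 30M_216, 30M_218 and 30M_220 (SD 0.147 at 6M), so 30M_216 was within the 6M spread. Ciliated, club, aerocyte, alveolar fibroblast and neuroendocrine lists were lower too (medians -0.25, -0.243, -0.33, -0.241 and -0.567). General capillary (0.177), large vessel (0.0627), adventitial fibroblast (0.0229), smooth muscle (0.0907) and mesothelium (0.462) were not. With the GC term and without the 3 GC libraries, however, general capillary was at -0.116 and -0.047 and smooth muscle at -0.159 and -0.187. Of these lists only general capillary genes lay above the alveolar lists by over 2 SD of 6M in each 30M library (0.238, 0.461 and 1.02; SD 0.112). That is 1 of 11 resident lists compared, and the smallest was at 2.12 SD. Smooth muscle genes lay -0.208 and mesothelium 0.107 above in 30M_216, and mesothelium -0.248 in 30M_220. Dilution and a change of these cells with age cannot be told apart here, as the 30M libraries disagree.

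Libraries were also regrouped. For pairs of ages there are 10 splits of 6 libraries, too few for a share under 0.05. At 30M against 6M, 1 of 10 splits gave 361 genes or more, the highest other giving 0, and 1 gave 27 lists, the highest other giving 26. At 20M against 6M, 1 gave 3 genes, the highest other giving 0, and 8 gave 16 lists or more, up to 25. At 12M against 6M all 10 gave 0 genes or more, the highest other giving 0, and 3 gave 22 lists, up to 27, and at 20M against 12M all 10 gave 0, with 0 as the highest other. At 30M against 20M, 2 gave 39 genes or more, and 3 gave 23 lists, up to 24. The other gene split gave 2867 and set 20M_213 with 30M_216 and 30M_218 against the 3 libraries with a steep GC trend, a structure of the samples; with that set as a term the ages gave 36 genes. Of 100 drawn splits of all 12 libraries, the real one included, 2 gave 494 trend genes or more. For genes differing among ages, 2 gave 205 or more. That share is under 0.05, but the highest others gave 638 and 1245, the latter several times the real count. A drawn grouping thus gave more genes than the ages did, so these draws do not exclude chance. Whether a structure of the samples lies behind those counts was not tested. For lists with a trend 10 of 100 gave 25 or more, up to 32, and chance is not excluded.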
